A study of Escherichia coli with 5 samples.

How the data were processed

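RNA was transcribed from plasmid pPR9 in 4 reactions in vitro or taken from cells of E. coli MG1655, per the labels, and reverse transcribed. The cDNA was amplified as 6 segments of about 200 bp with a 6 nt barcode for each library. Stretches at the segment ends, which RNA polymerase errors cannot reach, served as an internal control for errors made after transcription. Whether this control covers errors of reverse transcription cannot be told from the rates. Standard Mg had barcode 1, Mn barcode 2 and in vivo barcode 5. Which of the remaining barcodes belonged to which of the GreAB libraries is not given in the sources used here. The design had 1 library in each of 5 groups, and the barcodes let all 5 be sequenced together.

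The deposited table gives an error rate as a fraction for each position and library, computed by the authors. CASAVA 1.4, Bowtie 0.12.7 and SAMtools 0.1.18 were used upstream, per the submitters' processing notes. Their settings, the filters on reads and bases and the denominator of the fraction are not given in the sources used here. The table covers 1008 of the 1274 positions of the region, 774 marked as cDNA (called transcript positions) and 234 marked as internal control. The reason why 266 positions have no rate is not given either. Per the file headers the table has the reference base only, so the rate of each of the 12 substitution types, which had been planned, could not be computed. Reads per position are not in the table. The depth is therefore unknown, no counting interval was computed, and a check on a minimum of reads could not be made. Transcript values carried 2 significant digits and control values 3. The largest possible rounding error was 5% for transcript and 0.5% for control values, with a median of 2.08% for transcript values. The rates ran from 3.2 to 6400 per 100000 nucleotides and none was 0.

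Fractions were multiplied by 100000, and T was written as U except in printed sequences. The region was placed on the plasmid of 10557 nt by exact matches of 12 bases, which gave the 6 segments. The base in the table equalled the base of the region sequence at every position. The reading frame of rpoB was the only one in the plasmid from ATG to a stop codon with the annotated length of 4029 nt, at plasmid positions 3166 to 7194. The upstream frame was placed by the annotated distance between rplL and rpoB. Each segment was split at its stretch without rates into an upstream and a downstream part, and values within parts are given beside those over all positions because the rates of these parts differed. Comparisons within parts and values by neighbouring base leave out region position 1092, the highest.

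For each library the mean, SD, median and quartiles over positions were computed, in all and by reference base, by purine or pyrimidine, in runs of at least 3 identical bases, and by the base before and after. Each comparison used the ratio of mean rates, the median and quartiles of the log2 ratio per position, the share of positions higher or lower, and the number of segments with the same direction. No pseudocount was needed. Base groups were set against 10000 random lists of positions of the same size, matched on mean rate in 10 strata, and the percentile is a description and not a test. No test across samples was made, because each group had 1 library. Correlations between libraries were computed across positions as Spearman's rho.

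Named positions were chosen by a rule. For each comparison these were the 10 with the largest rise and the 10 with the largest fall in the ratio of rates among the 394 positions at or above the median mean rate of 20.6, and also the 10 highest in each library. The text gives the leading ones of each list, with 5 bases on both sides. Groups, comparisons, this rule and the first set of other settings were fixed before the data were examined. The position 1092 and the comparison of GreAB/Mn with GreAB/Mg were singled out afterwards, as were the edges of the parts.

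The other settings fixed in advance were the median in place of the mean, leaving out the 1% of positions with the highest rates (8 positions), leaving out 10 transcript positions at both ends of each segment (120 positions), subtraction of the control rate, leaving out each segment in turn, a pseudocount of 8.17 per 100000 (the percentile 5 of standard Mg), a filter at the median rate, another neighbouring base, Pearson's r of log10 rates, and ranking by difference. Settings chosen after seeing the data were leaving out position 1092, leaving out 10 positions at both ends of each part (240 positions), and subtraction of the control's log2 ratio, over all control positions or those more than 3 bases from the transcript part. A value counted as moved when it differed from the main value by more than the SD of that value over the 6 segments, since there were no replicates.

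The method was tested on simulated data, in which the rates at the 191 G positions were multiplied by a known fold and noise was added. Folds of 1, 1.1, 1.25 and 1.5 were recovered as mean ratios of 0.999, 1.10, 1.25 and 1.50 over 20 draws each. The group's median lay above percentile 97.5 in 1 of 20 draws without a change and in 20 of 20 draws at each of the other folds. Noise was drawn for each position alone, so a shift of a whole base group in a single library was not simulated. The recovery therefore does not show that such folds exceed differences between single libraries. Values were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures drawn with matplotlib 3.10.9.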

Results

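The fidelity of Escherichia coli RNA polymerase was measured on a single transcript, made from plasmid pPR9 under the lambda phage PR promoter, by deep sequencing of cDNA. The transcript was 5.7 kb long and began upstream of rpoB, the gene for the β subunit of RNA polymerase itself. There were 5 libraries, with 1 library in each group. The standard reaction in the test tube held 5 mM MgCl2. The Mn reaction held manganese in place of magnesium, a metal known to loosen nucleotide selection by polymerases. GreA and GreB, cleavage factors that help the polymerase cut back the 3′ end of the RNA, were added with magnesium (GreAB/Mg) and with manganese (GreAB/Mn). The in vivo library came from RNA of cells whose promoter had been switched on at 42 °C. The chromosome of these MG1655 cells holds rpoB as well. Whether RNA of that copy entered the in vivo library cannot be told from the rates. With 1 library per group there was no replicate check, so sizes, spreads over positions and agreement between segments are given without p-values.

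Error rates stood at 774 positions of the transcript and at 234 internal control positions at the ends of the amplified segments. By design the control positions carried errors of library preparation and sequencing but none of RNA polymerase. Whether they carried errors of reverse transcription cannot be told from the rates. The 6 segments were joined into 1 sequenced region, and region positions are counted from 1 at its first base. Segments 1 and 2 covered plasmid positions 2315 to 2512 and 2781 to 2994, in a leader, a reading frame of 516 nt upstream of rpoB and the 319 nt between rplL and rpoB. The other 4 segments lay in rpoB (b3987), at codons 87 to 161, 175 to 244, 323 to 400 and 466 to 533. Plasmid positions are counted from 1 at the start of the plasmid sequence. The plasmid and region sequences differed at 2 places, G2389C and G2456C, with the plasmid's base first and the region's base last. Rates are given as errors per 100000 nucleotides. Read depth is unknown because the values are fractions without counts, so no counting interval can be given.

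Rates at transcript positions were low and similar in all 5 libraries. The mean was 30.9 errors per 100000 nucleotides with standard Mg (SD over positions 44.0), 33.2 with Mn (SD 40.2), 31.0 with GreAB/Mg (SD 57.1), 33.6 with GreAB/Mn (SD 85.1) and 38.5 in vivo (SD 232). A single A in rpoB, at region position 1092, set the order of the highest means. Without it the means were 29.9, 32.5, 29.3, 30.8 and 30.3 in the same order. Medians ran from 19 to 22, with 20 both with standard Mg and in vivo. The control positions had higher means of 42.2, 39.6, 39.9, 39.6 and 49.2.

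**Figure D1:**
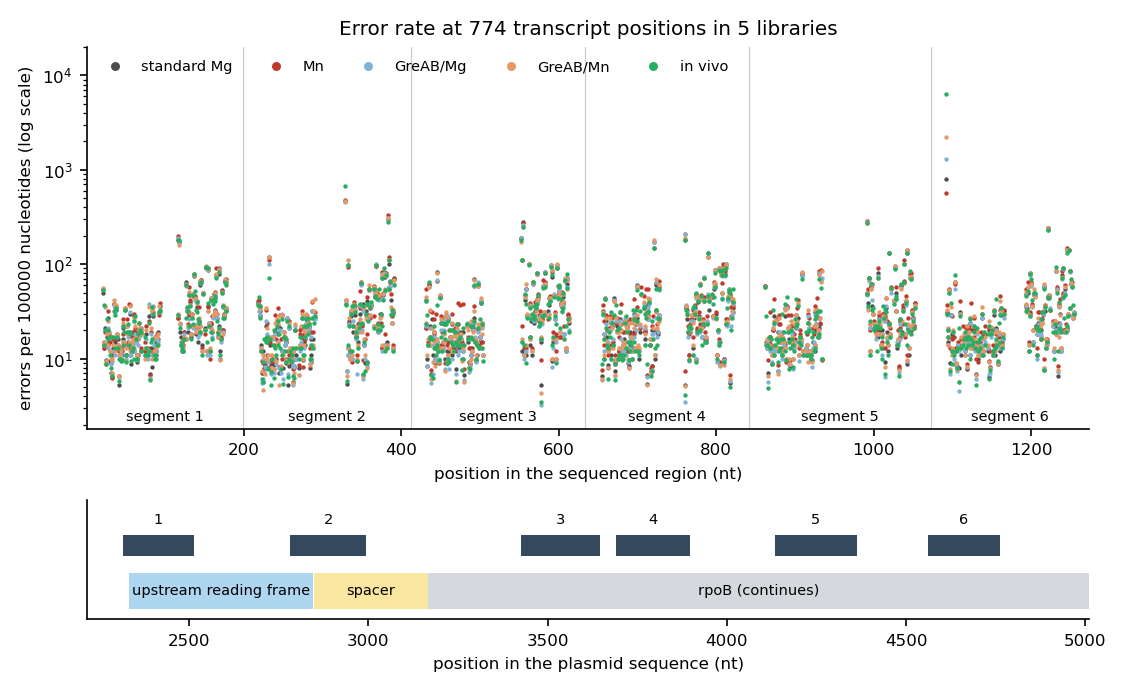
Error rate of each transcript position (errors per 100000 nucleotides, log scale) along the sequenced region (nt), with 1 point per position and library, above a map of the 6 segments on the plasmid (nt). Region position 1092 in segment 6 reached 6400 in vivo, against 800 with standard Mg.

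U carried the most errors of the 4 bases in the standard reaction and A and C the fewest. The mean was 37.6 at the 188 U positions, 30.2 at the 191 G positions, 28.1 at the 203 A positions and 27.8 at the 192 C positions. At control positions, which errors of RNA polymerase do not reach, U was also highest with 50.5, followed by C with 41.2, G with 40.2 and A with 34.3. Purines had a mean of 29.1 and pyrimidines one of 32.7. Rates also differed by the base before. C after C had a mean of 41.6 and U after U one of 43.0. The former included the C at region position 329, the first after the stretch without rates in its segment, with 470. A after G, without position 1092, had 18.8 and C after U had 19.6. G after C had 35.8 and G after A had 20.2. At control positions, over 11 to 17 positions each, C after C had 33.95, U after U 54.5, A after G 30.8, C after U 41.2, G after C 49.8 and G after A 51.1. By the base that followed, again without position 1092, means ran from 17.1 at A before U to 41.7 at U before U. The 128 positions within runs of 3 or more identical bases had a mean of 28.6 with standard Mg, against 31.3 at the other 646 positions, and medians of 17 against 20. In vivo the medians were 17 against 21. Positions downstream of the stretch without rates in each segment had 2.04 times the mean rate of those upstream with standard Mg, and 1.26 times in vivo, where position 1092 lay in the upstream part. The ratio of the medians was 2.00 and 1.94. At control positions the ratio of means was 1.43 and 1.48.

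**Figure D2:**
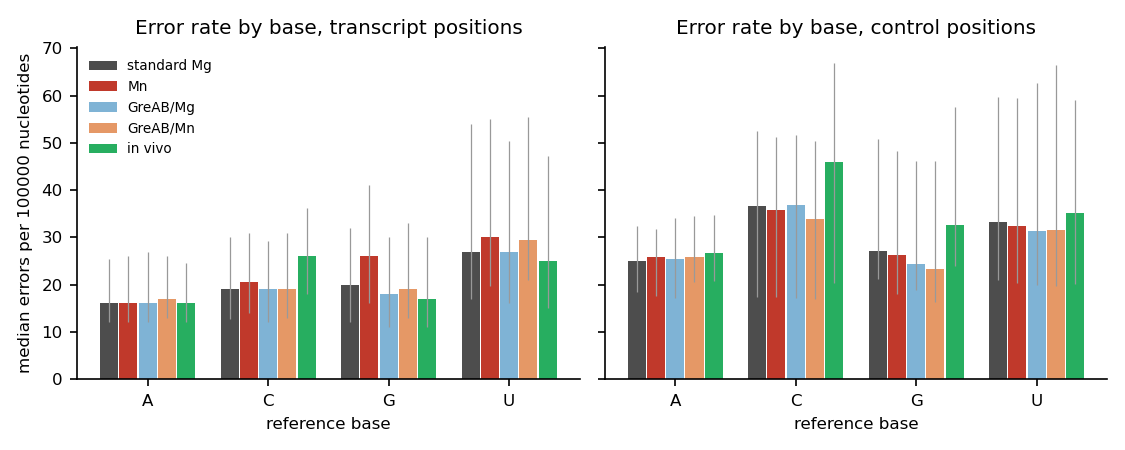
Median error rate (errors per 100000 nucleotides) of the positions of each reference base in each of the 5 libraries, with lines from the lower to the upper quartile of the positions, for transcript and control positions. At transcript G positions the Mn bar (26) exceeds the standard Mg bar (20), and at C positions the in vivo bar (26) exceeds the standard Mg bar (19).

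The same positions had high rates whichever way the RNA had been made. Across the 774 positions, Spearman's rho between libraries lay between 0.876 and 0.985 in the 10 pairs, with 0.914 to 0.984 at control positions. Within the upstream parts rho was between 0.743 and 0.967, and within the downstream parts between 0.944 and 0.992. Positions are not independent replicates. Of the 10 positions with the highest rate in each library, 9 were shared by all 5 libraries. They included the C at region position 329 in the spacer before rpoB (CCAGCCTTTTT), with rates from 460 to 480 in the 4 in vitro libraries and 680 in vivo. The C at 383 (CTGTGCCTTTC) had rates from 280 to 330. In rpoB, the A at 555 in codon 135 (ACGGTACCTTT) had rates from 250 to 280, and the G at 991 in codon 373 (CCCTGGCGAGC) had rates from 270 to 290. The G at 1222 in codon 515 (TTTATGTACCA) stood at 230 or 240 in every library. Of these 9 positions, 5 were the first position after the stretch without rates in their segment.

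Replacing magnesium with manganese tests how the metal in the active site affects fidelity. With Mn, G, U and C positions had higher error rates, G most of all and C least, while A positions did not differ. At G the mean was 36.4 per 100000 with Mn and 30.2 with standard Mg, a ratio of 1.20. The rate was higher with Mn at 91.6% of the 191 G positions, with a median log2 ratio of 0.32 (interquartile range 0.17 to 0.51) and the same direction in 6 of 6 segments. U positions had means of 40.4 and 37.6, a median log2 ratio of 0.15, and higher rates with Mn at 78.2% of 188 positions. C positions had means of 29.2 and 27.8 and a median log2 ratio of 0.09. The median log2 ratio was 0.00 at A.

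G positions preceded by C stood out. At the 58 such positions the mean rate was 46.7 with Mn and 35.8 with standard Mg, a difference of 10.9 (SD over positions 5.58), and 96.6% were higher. The difference was 3.09 at G after A, 4.54 at G after U and 4.76 at G after G. Control G after C had 48.9 against 49.8, and control G after A had 43.0 against 51.1. U after C was also higher, with a difference of 5.78 over 55 positions of which 98.2% were higher. C after C had a difference of 2.48. The difference at all G positions was 6.27 in the upstream parts and 5.93 in the downstream parts, and at G after C it was 11.3 and 10.1. Against 10000 random lists of positions of like mean rate, the median of G lay at percentile 100, that of U at 100, that of C at 0.775 and that of A at 0.

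Among the 394 positions at or above the median mean rate, the 10 with the largest rise were 8 G and 2 U, and 9 of them followed a C. Their ratios ran from 1.5 to 1.95. The first was the G at region position 1124, plasmid position 4612, base 1 of rpoB codon 483 (TGGGCGATCTG), with 39 per 100000 against 20. The G at 347 in the spacer before rpoB (AAGGCGCCAGT) had 52 against 30, and the G at 998 in codon 375 (GAGCCGCCGAC) had 62 against 36. The G at 472 in codon 107 (TGAGCGCGAAG) had 39 against 23. The 10 largest falls had ratios from 0.713 to 0.893 and held 3 A, 3 C, 3 U and 1 G. They began with the A at 1092, at 570 against 800, the C at 360 (CGTTTCACACT), at 27 against 34, the A at 374 (TGACTACTGCT), at 24 against 30, and the U at 446 in codon 98 (CGCGTTAAACT), at 66 against 82.

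Over all transcript positions the mean with Mn was 1.08 times that with standard Mg, with a median log2 ratio of 0.12 (interquartile range 0.00 to 0.27) and higher medians in 6 of 6 segments. The median was 0.16 in the upstream and 0.08 in the downstream parts. Control positions had a ratio of 0.939 and a median log2 ratio of -0.02, and control G positions one of -0.04. Set against the ratio of means of control G, the G value went from 0.27 to 0.38 on the log2 scale, or to 0.40 with control G more than 3 bases from the transcript part. The rates were given to 2 significant digits, which moves a rate by up to 5%, so small ratios at a single position carry little weight.

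**Figure D3:**
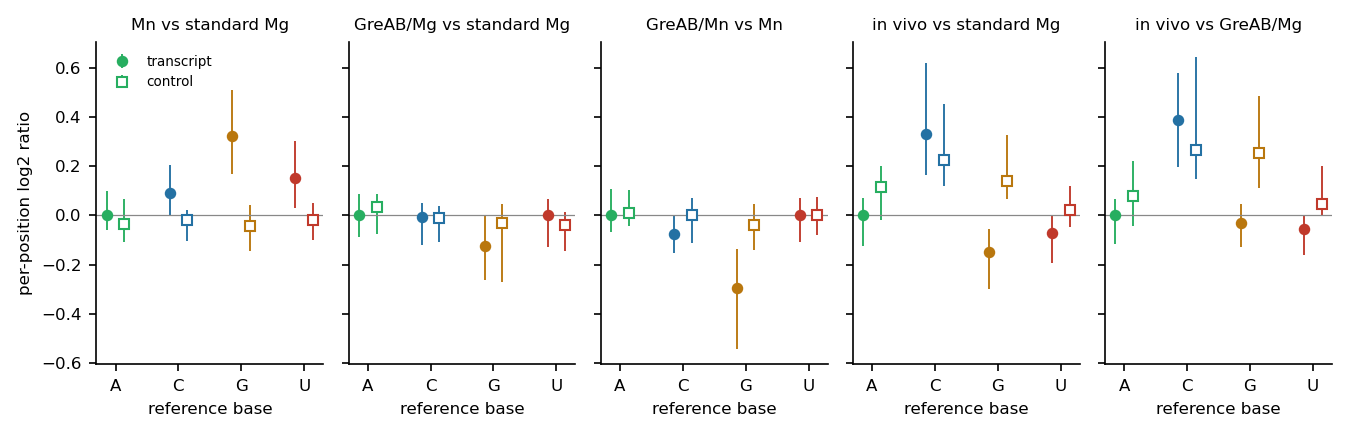
Median log2 ratio of the error rate per position (lines from the lower to the upper quartile) by reference base for 5 comparisons of libraries, with filled points for transcript and open squares for control positions. G stands at 0.32 for Mn against standard Mg and at -0.30 for GreAB/Mn against Mn, while control G stands at -0.04 in both.

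GreA and GreB were added to the magnesium reaction to ask whether RNA cleavage removes errors. With magnesium the difference was small and was seen mainly at G. The mean at control G was lower too, at 34.7 with GreAB/Mg against 40.2 with standard Mg. The mean at G was 28.7 with GreAB/Mg and 30.2 with standard Mg, a ratio of 0.950, and 69.6% of G positions were lower. The median log2 ratio at G was -0.13 (interquartile range -0.26 to 0.00), lower in 6 of 6 segments, against -0.01 at C and 0.00 at both A and U. G after C was again the most affected, with a mean difference of -2.92 (SD over positions 3.76). Control G after C had 47.7 against 49.8, and control G after A had 33.2 against 51.1.

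The 10 largest falls with GreAB/Mg were 6 G and 4 U, and 9 of them followed a C. Their ratios ran from 0.478 to 0.778. The G at region position 472 (rpoB codon 107) had 11 per 100000 against 23. The U at 439 in codon 96 (ACCGCTGCGCG) had 17 against 26, the G at 679 in codon 190 (GATCCGAAGGA) had 16 against 23, and the U at 379 in the spacer (ACTGCTGTGCC) had 52 against 74. The largest rises with GreAB/Mg were led by A positions. The A at 934, plasmid position 4226 in codon 354 (TGTCGACCCAA), had 71 against 10, which is 7.10 times as high. The A at 24 in the reading frame upstream of rpoB (GGAACAACGCA) had 35 against 21, and the A at 1092 had 1300 against 800. The control bases with the largest rises in both GreAB libraries, named here after their values were seen, lay at the start of segment 2. The control A at 199 had 46.9 against 12.9, and the control A at 200 had 16.1 against 9.16.

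Over all positions the ratio of means was 1.00, or 0.982 without position 1092, and the median log2 ratio was -0.03 (interquartile range -0.14 to 0.06), with lower medians in 5 of 6 segments. The mean difference at G was -1.63 in the upstream and -1.33 in the downstream parts. Control positions had a ratio of 0.944 and a median log2 ratio of -0.02. The mean at control G positions was also lower with GreAB/Mg, by a difference of -5.49, although their median log2 ratio was -0.03. Set against the control's ratio of means, the transcript G ratio was 0.14 on the log2 scale, while the median set against the control's median was -0.09, so the direction turned with means and not with medians.

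With manganese the difference between the libraries with and without GreAB was larger than with magnesium, and it was seen mainly at G. The mean at G was 30.3 with GreAB/Mn and 36.4 with Mn, a ratio of 0.835, and 89.0% of the 191 G positions were lower. The median log2 ratio at G was -0.30 (interquartile range -0.54 to -0.14), lower in 6 of 6 segments. The G mean with GreAB/Mn was close to the 30.2 of the standard reaction. U and A positions had a median log2 ratio of 0.00 and C positions one of -0.08, so the higher U rate with manganese, 40.1 against 37.6 with standard Mg, was still present with GreAB/Mn.

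G after C had a mean of 35.1 with GreAB/Mn and 46.7 with Mn, a difference of -11.6 (SD over positions 7.12), with -12.0 in the upstream and -10.9 in the downstream parts. G after A differed by -2.07 and G after U by -4.50. Control G after C had 48.0 against 48.9, and control G after A had 31.7 against 43.0. The 10 largest falls were all G, and 9 of them followed a C, with ratios from 0.410 to 0.659. The G at 472 had 16 against 39, the G at 1124 had 17 against 39, the G at 347 had 26 against 52, and the G at 679 had 20 against 38. The positions that were higher with GreAB/Mn began with the A at 934, at 85 against 9.7, the A at 1092, at 2200 against 570, and the A at 24, at 36 against 19. The control A at 199 had 69.7 against 13.5, and the control A at 200 had 25.5 against 6.8.

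Over all positions the ratio of means was 1.01, or 0.946 without position 1092, and the median log2 ratio was -0.06, with lower medians in 5 of 6 segments. The mean difference at G was -5.76 in the upstream and -6.34 in the downstream parts. The control ratio was 1.00 with a median log2 ratio of -0.01, and control G positions had a median of -0.04 and a ratio of means of 0.924. Set against that ratio, the transcript G value went from -0.26 to -0.15 on the log2 scale, or to -0.11 with control G more than 3 bases from the transcript part. This comparison and that of Mn against standard Mg share the Mn library, so a chance value of that library enters both with opposite sign.

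**Figure D4:**
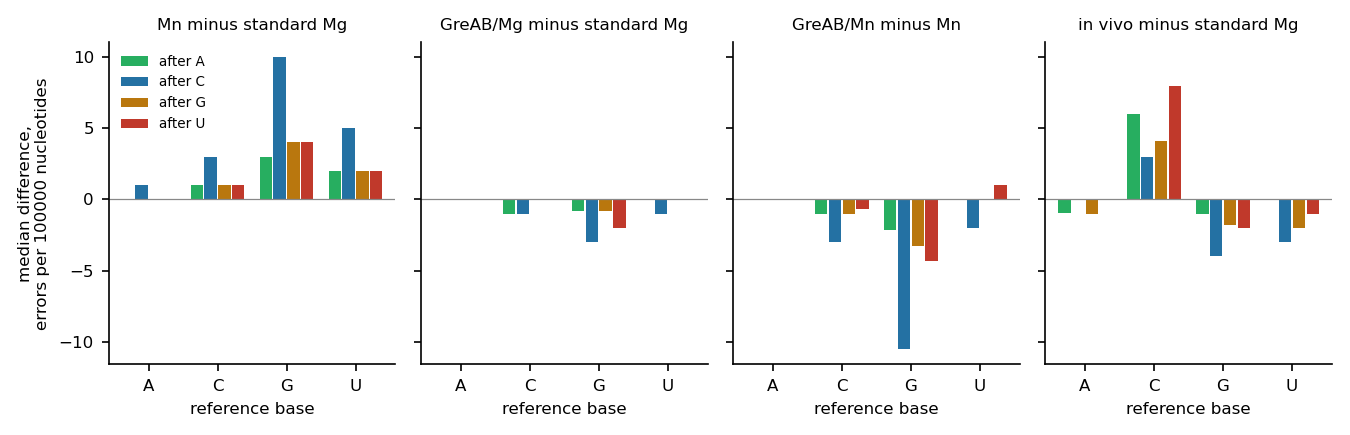
Median difference in error rate (errors per 100000 nucleotides) at transcript positions, by reference base and the base before it, for 4 comparisons of libraries. G after C reaches 10.0 for Mn minus standard Mg and -10.6 for GreAB/Mn minus Mn, and C after U reaches 8 for in vivo minus standard Mg.

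The 4 in vitro libraries form a square of metal and Gre factors, which allows the Gre effect in manganese to be set against that in magnesium. The Gre effect at G was stronger in manganese. The log2 ratio of means at G in manganese minus that in magnesium was -0.19, with a median over positions of -0.19 (interquartile range -0.37 to -0.07). It was lower at 156 and higher at 32 of the 191 G positions, and lower in 6 of 6 segments. In rates, the difference of differences at G was -4.51. It was 0.30 at U and -0.73 at C, and control G positions had a median log2 value of 0.03. Set against the control's ratio of means, the value at G was -0.29. The Mn library enters this value as well. A high G rate in that single library would give it together with the rise with Mn and the fall with GreAB/Mn. Over all transcript positions the value was 0.01 and turned to -0.055 without position 1092, with a median of -0.03.

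**Figure D5:**
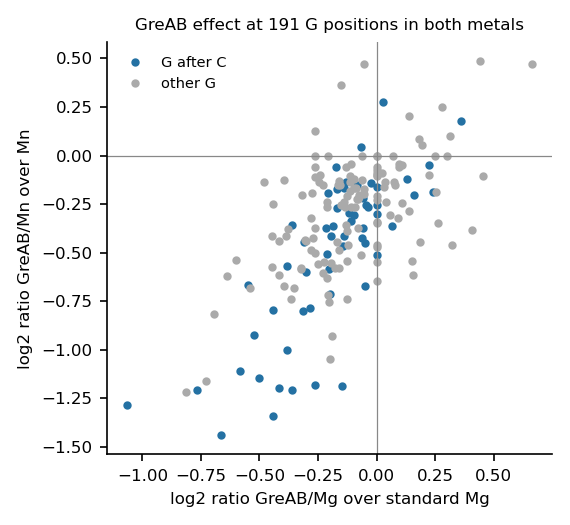
Log2 ratio of the error rate with and without GreAB at each of the 191 transcript G positions, in manganese (vertical axis) against magnesium (horizontal axis), with blue points for G after C. Spearman's rho over these positions was 0.575, and the lowest points include the G at 472, at -1.06 and -1.29.

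Transcripts from cells were compared with the standard reaction to set fidelity in the test tube beside that in vivo. In cells, C positions had higher error rates while G and U positions had lower ones. The mean at C was 34.5 in vivo and 27.8 with standard Mg, a ratio of 1.24. The rate was higher at 89.1% of the 192 C positions, with a median log2 ratio of 0.33 (interquartile range 0.16 to 0.62) and 6 of 6 segments higher. At G the median log2 ratio was -0.15, with lower rates in vivo at 79.1% of positions and in 6 of 6 segments. At U it was -0.07, with 64.9% lower in 5 of 6 segments, and at A it was 0.00.

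C after U differed most, with a mean of 27.5 in vivo and 19.6 with standard Mg, and 97.8% of the 46 positions were higher. Control C after U had 57.1 against 41.2, and control C after G had 52.9 against 33.1. The median log2 ratio was 0.64 at C after U, 0.42 at C after A, 0.32 at C after G and 0.18 at C after C. G after C, the group most affected by manganese, had a mean difference of -4.23, and U after C one of -3.96. The mean difference at C was 5.90 in the upstream and 7.58 in the downstream parts. At G it was -2.60 and -2.39, and at U it was -2.58 and -1.92. Control C positions were also higher in vivo, with a ratio of 1.38 and a median log2 ratio of 0.23. The ratio was 1.34 at the 49 of them more than 3 bases from the transcript part, and the control's median at G was 0.14. Set against the control's ratio of means, the transcript C ratio was -0.16 on the log2 scale, while the median set against the control's median was 0.10, so the direction at C turned with means and not with medians. At G the ratio of means went from -0.13 to -0.37 and the median from -0.15 to -0.29 when set against the control in the same way.

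The 10 largest rises in vivo were 9 C and the A at 1092, which had 6400 per 100000 against 800. The C at 1156, plasmid position 4644 in codon 493 (ATGATCAACGC), had 43 against 21, and the C at 139 in the upstream reading frame (TATACCACCGT) had 33 against 18. The C at 129 in that frame (AATCACTGGAT) had 32 against 19. The C at 703 in codon 198 (CGTATCGACCG) had 32 against 19. The largest falls had ratios from 0.451 to 0.659 and held 5 U, 3 G and 2 A. The U at 446 (codon 98) had 37 against 82, the G at 679 had 11 against 23, the U at 880 in codon 336 (AACGCTGTTCA) had 12 against 23, and the G at 232 in the upstream reading frame (CTCTGGAAGAA) had 72 against 120. Over all positions the ratio of means was 1.248, but 1.01 without position 1092, and the median log2 ratio was 0.00 (interquartile range -0.15 to 0.14). The A ratio of 1.97 likewise rested on that position and was 0.988 without it.

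Cells hold Gre factors, so the in vivo library was also set against GreAB/Mg. The C difference was as large as against standard Mg. The mean at C was 34.5 against 27.3, a ratio of 1.26, with a median log2 ratio of 0.39 (interquartile range 0.20 to 0.58), higher rates at 94.3% of positions and 6 of 6 segments higher. At G the median log2 ratio was -0.03, with 52.4% of positions lower, and at U it was -0.06, with 60.1% lower. The mean difference at C was 6.08 in the upstream and 8.51 in the downstream parts. The 10 largest rises were again 9 C and the A at 1092, at 6400 against 1300, with ratios from 1.48 to 4.92. The largest falls began with the A at 934, at 10 against 71, the U at 446, at 37 against 68, and the A at 24, at 20 against 35.

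Over all positions the ratio of means to GreAB/Mg was 1.24, or 1.03 without position 1092, with a median log2 ratio of 0.00. Control positions had a ratio of 1.23 and a median log2 ratio of 0.17, and control C positions a median of 0.27. Set against the control's ratio of means, the transcript C ratio was -0.16 here too, and the median set against the control's median was 0.12. At G the ratio of means went from -0.052 to -0.51 and the median from -0.030 to -0.29. Both comparisons rest on the same in vivo library and are not independent.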

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

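All tests in this part were chosen after the results were seen. The control positions, which no comparison of the report was about, had higher mean rates in vivo than in the 4 in vitro libraries, except at U. The ratio of the in vivo mean to that of standard Mg was 1.17 over all control positions (49.2 per 100000 against 39.6 to 42.2 in vitro). It was 1.20 at control A (41.0 against 32.3 to 35.8, with medians of 26.7 in vivo and 25.1 with standard Mg), 1.38 at control C (56.9 against 39.9 to 41.2) and 1.19 at control G (47.7 against 34.3 to 40.2). At control U it was 0.979.

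The first pattern weighed was the higher C rate in vivo, at transcript and control positions alike. Transcript errors counted at control bases beside the transcript part are argued against for the 49 control C positions more than 3 bases away, with a median log2 ratio of 0.21 (interquartile range 0.11 to 0.38), but cannot be told apart for the 9 nearer ones, too few to decide, with 0.95. Damage to double-stranded DNA would raise C and G alike. Control G was higher, with a median of 0.14 (interquartile range 0.07 to 0.32). Transcript G was not, with -0.15 (interquartile range -0.30 to -0.05), and with -0.03 against GreAB/Mg. A lower G rate from another source could mask a rise there, so damage stays open in the transcript too. An added error that the control shares stays open, since the median difference at control C was 7.8 per 100000 against 5 at transcript C (SD over segments 1.37), so the C rise in vivo may not come from transcription. A difference between RNA made in cells and in vitro also stays open, untested beyond the control.

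The next pattern was the higher G rate with Mn and its return when GreAB was added. Errors that the control positions share are argued against at G. Control G had a median log2 ratio of -0.041 (interquartile range -0.14 to 0.04) against 0.32 in the transcript. The control lay only at the segment ends, so PCR errors confined to inner bases are not excluded by it. Manganese carried over alike into reverse transcription is argued against for G, where the rise from GreAB/Mg to GreAB/Mn was 1.62 per 100000 (SD over segments 0.687) against 6.13 without GreAB (SD 1.54). For U that carry-over could be the source and stays open, since the rise was 3.14 with and 2.84 without GreAB. A fault of the single Mn library cannot be told apart from an effect of the metal at G, because each condition had 1 library, although G was also higher in the GreAB pair by a median log2 ratio of 0.11.

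The last pattern was the A at region position 1092, the first transcript base of segment 6, with 800, 570, 1300, 2200 and 6400 per 100000 in standard Mg, Mn, GreAB/Mg, GreAB/Mn and in vivo. An effect at the first transcript base of every segment is argued against, because the highest ratio of in vivo to standard Mg at the other 5 such bases was 1.35, against 8 here. A variant in 1 plasmid stock shared by the 4 in vitro reactions is argued against by a highest rate 3.86 times the lowest among them, where the 8 other leading positions stayed within 1.17. Differences between the primers of the libraries cannot be told apart from the groups, since each library had its own barcode, and the control base at 1090 varied 2.52 times over the libraries, although 1091, beside the position, varied 1.31 times, and 37 other control bases of that segment varied by a median of 1.15 and at most 1.796. No biological explanation was tested.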

How the results depend on the processing

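Of the values that answer a comparison, 277 under choices fixed in advance and 95 under those chosen after seeing the data moved by less than the SD over the 6 segments. Another 31 and 21 moved by more, and 5 and 6 reversed. A change of sign counted as a reversal only where the value exceeded that SD. Among smaller values 14 and 9 also changed sign or went to or from 0. Without position 1092 the overall ratio went from 0.0056 to -0.026 for GreAB/Mg against standard Mg and from 0.015 to -0.080 for GreAB/Mn against Mn, and the Gre effect in Mn against Mg went from 0.0092 to -0.055. With segments 1 to 5 left out in turn, each value stayed within that SD. Leaving out 1 of 6 similar segments can hardly move a value by more than the SD over them, so this check had little chance to fail. Its values are part of the 277. Segment 6, which holds position 1092, also widened the SD for some values. The log2 ratio of in vivo to standard Mg over all positions was 0.32, with an SD over segments of 0.48, and 1.20 in segment 6. It went to 0 with the median over positions and as low as 0.016 with a segment left out. Both counted as moved by less than the SD. The settings chosen after seeing the data were those without position 1092, without the edges of the parts, and minus the control's log2 ratios, of all its positions or of those more than 3 bases from the transcript part. The rates per position could not be tested against depth, which is unknown, and log2 ratios after subtraction of the control rate were not computed because rates below 0 arose. For all changed values below the cause was not tested, except where position 1092, an A, was left out.

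The log2 ratio of means at A in vivo (0.98 against standard Mg, 0.83 against GreAB/Mg) reversed to -0.018 and -0.047 without position 1092, to -0.023 and -0.050 without 10 transcript positions at each segment end, to -0.026 and -0.063 without segment 6, to -0.010 and -0.039 without the 1% highest positions, and to -0.011 and -0.011 without 10 positions at both ends of each part. Without the 1% highest positions the overall means of standard Mg, Mn and GreAB/Mg were 27.6, 30.2 and 27.1. Without 10 positions at both ends of each part the means of standard Mg, Mn, GreAB/Mg and GreAB/Mn were 26.1, 28.8, 25.4 and 26.9, and the difference at G after C for GreAB/Mn minus Mn was -13.4.

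With the median over positions, the overall rates of standard Mg, Mn, GreAB/Mg and GreAB/Mn were 20, 22, 19 and 21. The log2 ratio for GreAB/Mg against standard Mg was -0.074. At C in vivo it was 0.45 against standard Mg and 0.45 against GreAB/Mg. At G it was 0.38 for Mn, -0.15 for GreAB/Mg and -0.45 for GreAB/Mn, and the Gre effect in Mn against Mg was -0.30.

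With the control rate subtracted, the overall rates of standard Mg, Mn, GreAB/Mg, GreAB/Mn and in vivo were -11.4, -6.40, -8.88, -6.05 and -10.7. The difference for GreAB/Mg minus standard Mg reversed to 0.374 at C, 3.99 at G and 2.56 at U, and the in vivo difference at C reversed to -9.05 against standard Mg and -9.42 against GreAB/Mg.

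With the control's log2 ratio of means subtracted, Mn against standard Mg was 0.20 and GreAB/Mg against standard Mg 0.088, with a reversal at C to 0.0044, at G to 0.14 and at U to 0.070. The in vivo ratio at C reversed to -0.16 against both. At G the values were 0.38 for Mn and -0.15 for GreAB/Mn, and the Gre effect in Mn against Mg was -0.29. With the control's median log2 ratio subtracted from the median, GreAB/Mg against standard Mg was -0.012, in vivo was -0.12 against standard Mg and -0.17 against GreAB/Mg, C in vivo was 0.10 and 0.12, and G with GreAB/Mg was -0.093. With control positions more than 3 bases from the transcript part, the ratio of means at C in vivo reversed to -0.11 against standard Mg and -0.12 against GreAB/Mg, and that at G was 0.40 for Mn, 0.18 for GreAB/Mg, a reversal, and -0.11 for GreAB/Mn. The medians were 0.12 and 0.14 at C in vivo and -0.043 at G with GreAB/Mg.

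At positions at or above the median rate, the median log2 ratio was 0.078 for Mn, 0.22 and 0.25 at C in vivo and -0.074 at G with GreAB/Mg. With the pseudocount these were 0.079, 0.23, 0.26 and -0.081.

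With a C at +2 in place of -1, the difference at G was 6.78 for Mn minus standard Mg, -5.86 for GreAB/Mn minus Mn and -0.809 for GreAB/Mg minus standard Mg, and at U it was 2.71 for Mn minus standard Mg. With a C at -2 these were 6.36, -4.81, -0.911 and 3.10. With a U at -2 the in vivo difference at C was 5.59. Ranking by difference kept 4 of the 10 rises and 6 of the 10 falls for Mn, 4 and 3 for GreAB/Mg, 6 and 5 for GreAB/Mn, 7 and 4 for in vivo against standard Mg, and 4 and 4 for in vivo against GreAB/Mg.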

Other observations

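The tests and the comparison in this part were chosen after the results were seen. With both Gre factors present, manganese still went with higher error rates at U. GreAB/Mn had a mean of 40.1 per 100000 at U against 37.0 with GreAB/Mg, a difference of 3.14, and 83.0% of the 188 U positions were higher with a median log2 ratio of 0.14. The direction was the same in 6 of 6 segments, and the mean difference was 3.58 in the upstream and 2.75 in the downstream parts. U after C differed by 4.67 over 55 positions. G differed by 1.62, with 72.8% of positions higher, and control positions had a median log2 ratio of 0.00.

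Some positions were higher in both GreAB libraries than in both libraries without GreAB. Ranked by the lowest of their 4 ratios, the first 5 transcript positions were the A at 934, 24 and 1092, the G at 70 (ACCAAGACAGC), with 19 and 18 per 100000 against 12 with standard Mg and 13 with Mn, and the G at 80 (CTAAAGATCCG), with 38 and 35 against 28 and 25. In vivo, the A at 934 had 10, the A at 24 had 20, the G at 70 had 12 and the G at 80 had 24. Position 934 was the last with a rate before the stretch without rates in segment 5. Control bases rose in the same way, led by the A at 199, with 46.9 and 69.7 against 12.9 and 13.5, and the A at 200, with 16.1 and 25.5 against 9.16 and 6.8. Such rises are thus not limited to bases that errors of RNA polymerase reach. The A at 199 and 200 lay at the start of segment 2. An effect at segment ends that differed between libraries was not separated from GreAB there.

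A hypothesis is that GreAB lowers errors at the same G positions in both metals, which may reflect cleavage at sites prone to error. Both effects were computed from libraries with none in common. Spearman's rho between them was 0.575 over the 191 G positions, 0.760 at G after C and 0.483 at other G, and 0.645 in the upstream and 0.322 in the downstream parts. It was 0.202 at control G, and 0.134, 0.219 and 0.194 at transcript A, C and U. Errors shared by all libraries would shrink both log2 ratios where they are common. With GreAB/Mg the median log2 ratio at G was -0.074 at positions at or above the median rate, against -0.13 at all G. G was lower with GreAB in both metals, so such shrinkage alone would give a positive rho. Groups with little shift would show less of it. The test therefore cannot tell particular G positions from a fall at G in general. Positions are not independent replicates, here and in the tests that follow.

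Another hypothesis is that manganese raises errors at U positions that GreAB leaves in place. The Mn effect at U with and without GreAB, again with no library in common, gave a rho of 0.427, with 0.428 in the upstream and 0.285 in the downstream parts and 0.0437 at control U. The same rho at G was 0.403. Shrinkage of both ratios by shared errors would give a positive rho here too, since U was higher with Mn in both pairs. Manganese carried over into reverse transcription could give the same pattern, so the step at which these errors arose stays open.

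U errors sensitive to the metal may also be rarer in cells. The log2 ratio of in vivo to GreAB/Mg and that of Mn to standard Mg gave a rho of -0.342 over U positions, with -0.255 and -0.358 in the upstream and downstream parts. It was 0.00493 at control U, -0.0269 at G and 0.158 at C. Errors shared by all libraries would shrink both ratios where they are common. U was higher with Mn and lower in vivo, so such shrinkage alone would give a negative rho. Groups with little shift would show less of it. The test therefore cannot decide whether the same U positions were involved.

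The C rise in vivo could depend on the codon base if translation or selection on the mRNA played a part. Over the 136 C positions in rpoB the median log2 ratio to standard Mg was 0.30, 0.31 and 0.39 at codon bases 1, 2 and 3. The highest and lowest differed by 0.088, and 61.05% of 10000 shuffles of the codon bases over these positions gave a difference as large. A dependence was not detected. The percentile 95 of the shuffles was about 0.18, which sets no limit on the size of a true dependence, so one stays open.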
